A study of Mus musculus with 12 samples.

How the data were processed

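Gene expression was measured by strand-specific polyA RNA sequencing in 12 libraries from astrocyte-enriched cortical cultures of newborn C57BL6/J mice. The cultures carried a control lentivirus (pCIG3, which expresses GFP) or a lentivirus for ACREB, a dominant-negative inhibitor of the transcription factor CREB, for 5 days. They then received PBS or 0.5 µM vasoactive intestinal peptide (VIP) for 30 min, with 90 min of recovery before lysis. The 4 combinations of virus and treatment had 3 libraries each, numbered 1 to 3 in the labels. The labels do not say whether the numbered replicates are separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

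The authors deposited raw counts per Ensembl gene, 1 column per library, with no normalization and no pooling. Per the submitters' processing notes, the tools were Trimmomatic 0.39, STAR 2.7.1a, HTSeq 0.11.2, R 3.6.1 and edgeR (version not given), with the GRCm38 (mm10) mouse genome. The strand setting of the counter and the annotation release are not given in the sources used here. Genes that overlap a gene on the opposite strand are therefore marked as uncertain. Total counts were 16571398 to 20529238 per library. The table held 55573 genes, of which 30838 had at least 1 count, and it had 0 entries that name no gene. A symbol was matched to 55394 gene identifiers and not to 179. Gene positions come from the GENCODE annotation of GRCm38.

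Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. edgeR's filterByExpr kept 16761 genes. Libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 12 libraries (residual degrees of freedom 8, prior degrees of freedom 3.99, common dispersion 0.0381). The contrasts were VIP against PBS within each virus, ACREB against control virus within each treatment, and the interaction, the VIP response with ACREB minus the VIP response with control virus. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Expression is given as CPM, counts scaled to library sizes adjusted by TMM, as mean ± SD over the 3 libraries of a group. A pseudocount of 2 was used for log2 CPM. The SE of a log2 fold change was derived as its absolute value divided by the square root of edgeR's F statistic, and is not a fitted standard error. Library composition was compared by two-sided exact permutation tests, for which 3 against 3 libraries allow a smallest p of 0.1.

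Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, all two-sided. The estimated correlation was used only in the fit without a block for the replicate number. The p of fry comes from limma's model and not from permutation, so exact tests or swaps of labels are given beside the main ones. Fry tests whether the genes of a list move on balance in 1 direction. P-values were adjusted over the 22 lists of a contrast. The lists were cAMP/CREB target genes, immediate-early genes, cAMP receptor and signalling genes, phosphodiesterases, glycogen metabolism, glucose uptake with glycolysis and lactate, circadian clock, secreted trophic factors and cytokines, sterol synthesis, interferon response, cell cycle, stress response, p53 target genes, mitochondrially encoded genes, and markers of astrocytes, reactive astrocytes, microglia, oligodendrocyte lineage, neurons, fibroblasts and mural cells, endothelium and ependyma. The groups, contrasts, tests, gene lists, naming rule and alternatives other than those added later were fixed before the data were examined. The rule named, for VIP in control virus and for ACREB with PBS, the 10 largest rises and 10 largest falls past the threshold with non-overlapping libraries and a mean CPM of at least 2 in the higher group, leaving out symbols of predicted or RIKEN genes. In the interaction it named the 10 most negative and 5 most positive genes under the same conditions that also passed for VIP in at least 1 virus, of which there were none, and the 5 genes past the threshold at log2 of at least 1 for VIP in both viruses with an interaction closest to 0. For the remaining contrasts it took 5 in each direction, and in every contrast up to 4 called members of each list. Members named because they passed adjusted over a list alone were chosen after their values were seen. One gene that the rule named is not reported here. The rule always included Creb1, Crem, Fos, Nr4a1, Per1, Sik1, Ppp1r3c, Gys1, Pygb, Gbe1, Vipr1, Vipr2, Adcyap1r1 and Gfap.

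The replicate numbers were checked for pairing. Same-numbered libraries deviated from their group means together in all 18 pairs, with correlations across genes from 0.132 to 0.679, and 12 of 12 libraries correlated best with a library of their own number. The numbers were therefore taken to pair the samples, and a fit with the number as a block (residual degrees of freedom 6) is given where it changes a call. No libraries were duplicates, since the chi-square per degree of freedom between libraries of a group was 13.2 to 98.1.

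Alternatives were DESeq2's size factors, library size without scaling factors, the DESeq2 test, no filter, a filter of CPM above 1 in at least 3 libraries, the block, the 6 libraries of a contrast alone, and leaving out each library in turn. Offsets for GC content and gene length (available for 16753 tested genes), alone and with the block, and leaving out both PBS libraries numbered 2 were added after the data were seen. The pipeline was tested on simulated counts for 16761 genes with 100 genes changed at each fold size. Only genes with a mean CPM above 1 were changed, and the simulated libraries had no effect of replicate number and no outlying library. For the interaction, all changed genes rose by 3 on the log2 scale with VIP in control virus. For VIP in control virus it recovered 65% of genes changed by 1 on the log2 scale and 99% of those changed by 2. For VIP with ACREB the values were 61% and 95%, for ACREB with PBS 66% and 92%, for ACREB with VIP 63% and 96%, and for the interaction 27% and 86%. A planned test of CREB binding motifs in promoters was not run because no genome sequence was used here.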

Results

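Total counts ranged from 16571398 to 20529238 per library. The group means were 18.6 ± 0.641 M counts (SD, n = 3) for control virus with PBS, 19.7 ± 0.816 for control virus with VIP, 17.1 ± 0.905 for ACREB with PBS and 18.5 ± 0.646 for ACREB with VIP. Exact permutation tests of depth, genes detected, the share of the 10 most abundant genes and the mitochondrial share gave two-sided p from 0.1 to 1, where 0.1 is the smallest possible. Control PBS library 2 stood apart, at 81.2 on a first principal component that held 38.1% of the variance. GC content and gene length explained 53.5% of the variance of its departure from the median library. ACREB PBS library 2 came next on that component, at 34.6, with 32.0% explained, and the other 10 libraries lay at 7.02 or below.

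Creb1 (ENSMUSG00000025958, chromosome 1, 64532645 to 64604548, GRCm38), the gene for CREB, was examined first, because ACREB carries the leucine zipper of CREB. Creb1 measured 67.2, 21.2 and 55.7 CPM in control PBS libraries 1 to 3 and 63.5, 55.0 and 45.4 CPM in control VIP libraries. It measured 104.1, 59.8 and 97.3 CPM with ACREB and PBS, and 117.4, 89.0 and 80.6 CPM with ACREB and VIP. The log2 fold change of ACREB over control was 0.86 with PBS and 0.81 with VIP, and neither passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.83 and 0.81). With GC and length offsets it passed at 0.74 (adjusted p = 0.015) and 0.86 (0.0044) in the same edgeR test. Counts per gene do not separate the transcripts of a transgene from those of Creb1, so ACREB expression itself was not measured.

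The first comparison asked which genes respond to VIP in the astrocyte-enriched cultures with control virus. VIP raised the orphan nuclear receptor Nr4a2 11.6-fold, from 5.02 ± 1.45 to 58.1 ± 3.95 CPM (SD, n = 3). Dio2, the deiodinase that activates thyroid hormone, rose 12.2-fold, from 5.16 ± 2.18 to 63.4 ± 37.1 CPM. Ppp1r3c, a glycogen-targeting subunit of protein phosphatase 1, rose from 45.8 ± 5.87 to 116.2 ± 24.3 CPM, while the notch glycosyltransferase Lfng fell from 176.3 ± 20.0 to 88.9 ± 20.6 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 71 genes rose and 11 fell, of which 53 and 1 changed by at least 1 on the log2 scale. The fit with the replicate block called 184 and 90, sharing all 82 calls and their direction, and DESeq2 called 186 and 71. With the 6 libraries of this comparison alone, edgeR called 2 and 0, and 26 of 27 named calls were lost.

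The log2 rises were 3.61 (SE 0.48, adjusted p = 0.0057) for Dio2 on chromosome 12 (90724552 to 90738438), 3.53 (SE 0.20, 1.04e-05) for Nr4a2 on chromosome 2 (57106830 to 57124003) and 1.34 (SE 0.18, 0.0057) for Ppp1r3c on chromosome 19 (36731731 to 36736653), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Tacr1, the substance P receptor, rose by 3.21, Trh, the precursor of thyrotropin-releasing hormone, by 3.16, and Zdbf2 by 2.99. Espn, an actin-bundling protein gene, rose by 2.71, and Kctd8 by 2.55. Tinf2 (2.65) and Trmt61b (2.22) also rose, but each overlaps a gene on the opposite strand, Gmpr2 and Spdya, so these counts are uncertain, and the locus listed as Trmt61b is itself annotated as antisense. The same holds for Dio2 and Gm26512, for Zdbf2 and Gm24513, for Kctd8 and Gm24368, for Txndc11 (1.85) and Snn, and for Crem (1.23) and Gm6225. Falls were found in Gpr146 (from 73.5 ± 13.7 to 36.7 ± 4.97 CPM), Lfng (-0.99), Fhdc1 (-0.95), Cdc42ep4 (-0.85), the Wnt ligand gene Wnt7a (-0.84), Stard8 (-0.78), Pdgfb (-0.72) and Dzip1l (-0.68). Cdc42ep1 (-0.75) fell as well but overlaps Lgals2.

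Among 30 tested cAMP/CREB target genes, 6 rose and 0 fell. They were Dio2, Nr4a2, Pde10a (2.16), Pde4d (1.68), Ppp1r3c and Crem. Adjusted over the list alone, 15 were higher and 1, Gadd45b (-0.72), was lower. The list was higher by camera (adjusted p = 2.67e-27), with an estimated correlation (adjusted p = 0.00047) and by fry (adjusted p = 0.00014). Of 14 phosphodiesterases, which degrade cyclic nucleotides, Pde10a and Pde4d rose, and the list was higher by camera (adjusted p = 1.32e-07) and with an estimated correlation (adjusted p = 0.034). Adjusted over the list alone, 4 phosphodiesterases were higher and 1 was lower. Pde10a, Pde4d and Pde4b are in this list and in the cAMP/CREB target list, so the lists are not separate results here or in the other contrasts.

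Of 31 glycogen metabolism genes only Ppp1r3c rose over all genes tested, and adjusted over the list alone Ppp1r3g (2.85) also passed, as it did over all genes with the block (adjusted p = 0.098, block 0.046, edgeR). The glycogen synthase gene Gys1 (-0.10, which overlaps Ruvbl2 on the opposite strand and is uncertain), the phosphorylase gene Pygb (0.02) and the branching enzyme gene Gbe1 (0.11) did not pass, and the list did not either (camera adjusted p = 0.315). Pfkfb3, which makes an activator of glycolysis, was the 1 of 28 glucose and lactate genes to fall (-0.52), with a list adjusted p of 0.261 by camera. The immediate-early transcription factor genes Maff (1.53) and Klf4 (0.96) rose among 28 immediate-early genes (camera adjusted p = 0.727). Adjusted over that list alone, 3 were higher and 2 were lower. Fos had a log2 fold change of 0.29, Per1 of 0.12, Nr4a1 of 1.41 and Sik1 of 1.19, and none of them passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.782, 0.882, 0.347 and 0.102). Nr4a1 passed with the replicate block (adjusted p = 0.0027, edgeR), and Sik1 passed with DESeq2 (adjusted p = 0.0019). The astrocyte marker Gfap (-0.07) and the receptor genes Vipr2 (0.30) and Adcyap1r1 (-0.24) did not pass, and Vipr1, with 69 counts over 12 libraries, was not tested.

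Gad1 (1.66), an enzyme of GABA synthesis, rose among 13 neuron markers. That list was higher by camera (adjusted p = 0.0096) and by fry (adjusted p = 0.0068, with the block 0.037), but not with an estimated correlation (adjusted p = 0.068), and with GC and length offsets and the block camera gave 0.073. Its median log2 fold change was 0.32 with all libraries and 0.08 without control PBS library 2, where the median neuron marker lay 0.45 below the median library after removal of the GC and length trend (-0.07 to 0.19 in the other 11 libraries). The interferon response list and the mitochondrially encoded genes were higher by camera only (adjusted p = 0.033 and 0.038), both with adjusted p = 0.579 with an estimated correlation. With the block, camera gave 0.078 for the mitochondrial list. The direction of that list turned with GC and length offsets (median -0.12, adjusted p = 0.898, and -0.11, 0.524 with the block too). Camera with the block also called the oligodendrocyte lineage markers lower (adjusted p = 0.026, without the block 0.129). With an estimated correlation, run without the block only, these markers had adjusted p = 0.579. The remaining lists did not pass camera. The adjusted p was 0.581 for cAMP receptor and signalling genes, 0.641 for the circadian clock, 0.727 for secreted factors, 0.261 for sterol synthesis and 0.471 for astrocyte markers. It was 0.156 for reactive astrocyte markers, 0.584 for microglia, 0.758 for fibroblasts and mural cells, 0.623 for endothelium, 0.727 for ependyma, 0.852 for cell cycle, and 0.987 for both stress response and p53 targets.

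The number of rises depended on single libraries, with 25 without control VIP library 1, 29 without control PBS library 1, 42 without control VIP library 2 and 45 without control VIP library 3. The count of falls was 0, 1, 1 and 6 in the same 4 fits and 7 without ACREB PBS library 2 or any 1 ACREB VIP library. Of 27 named calls, 20, 19, 14 and 11 were lost without control VIP library 1, control PBS library 1, control VIP library 2 and control VIP library 3, and 3 to 7 without each of the other libraries. Nr4a2, Dio2, Pde10a, Ppp1r3c, Maff, Tinf2 and Trmt61b passed in every fit that left out 1 library. Camera lost the interferon list without control PBS library 3 (adjusted p = 0.360) or control VIP library 2 (0.057) or 3 (0.064), and the mitochondrial list without control PBS library 1 (0.124) or 3 (0.065) or control VIP library 2 (0.623).

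The second comparison asked what VIP did in the astrocyte-enriched cultures with the ACREB virus. Nr4a2 rose 4.98-fold, from 4.23 ± 0.851 to 21.1 ± 0.954 CPM (SD, n = 3), and Txndc11, a thioredoxin domain protein gene, rose from 24.1 ± 2.50 to 50.2 ± 1.86 CPM. The log2 rises were 2.32 (SE 0.20, adjusted p = 0.0010) for Nr4a2 and 1.06 (SE 0.13, 0.020) for Txndc11, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These 2 genes were the only calls, with 0 falls, against 13 rises and 0 falls with the replicate block and 25 and 2 with DESeq2. At an unadjusted p under 0.05, edgeR gave 214 higher and 108 lower genes. A uniform spread of p-values would give 838.05 in all, but this count was not measured under regrouped labels for this contrast.

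Of 30 cAMP/CREB target genes, Nr4a2 rose over all genes tested, and adjusted over the list alone 6 were higher, among them Pde10a (1.32), Dio2 (2.24) and Ppp1r3c (0.78). The list was higher by camera (adjusted p = 1.16e-19), with an estimated correlation (adjusted p = 0.0015) and by fry (0.011, with the block 0.061). Phosphodiesterases were higher by camera (adjusted p = 1.84e-06) but not with an estimated correlation (adjusted p = 0.057). Reactive astrocyte markers and mitochondrially encoded genes were higher and sterol synthesis genes lower by camera only, with adjusted p = 0.126, 0.178 and 0.755 with an estimated correlation. Reactive astrocyte markers lost the call without ACREB PBS library 3 (adjusted p = 0.078), and sterol synthesis without ACREB PBS library 1 (0.072) or 2 (0.377) or ACREB VIP library 1 (0.098) or 3 (0.156). The call of Txndc11 was lost without ACREB PBS library 1 or 3 (adjusted p = 0.263 and 0.228) or ACREB VIP library 1, 2 or 3 (0.170, 0.094 and 0.132), all by edgeR, and the count of rises was then 1. It was 4 without control PBS library 2 and 5 without control VIP library 1.

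The third comparison, the interaction, asked how far the VIP response depends on CREB. Genes raised by VIP had smaller fold changes with ACREB. Nr4a2 rose 11.6-fold with control virus and 4.98-fold with ACREB, and the log2 rise of Txndc11 was 1.85 and 1.06. The fold of VIP over PBS was 4.48 and 2.50 for the phosphodiesterase gene Pde10a, 12.2 and 4.71 for Dio2, and 2.54 and 1.72 for Ppp1r3c, with the second value of these 3 genes not past the threshold. With the replicate block, VIP raised Pde10a (adjusted p = 0.060, block 0.0069) and Dio2 (0.376, block 0.048) with ACREB too, by edgeR. Over the 48 genes with a mean VIP effect of at least 1 on the log2 scale, the median was 1.78 with control virus and 1.05 with ACREB, or 58.9% of it. The difference was negative for 46 of the 48 genes, with a median of -0.67 and a fry p of 0.015. Selecting on the mean of both viruses does not favour a smaller response in either. Over the 53 genes chosen in control virus alone, which does, the medians were 1.53 and 0.84 (55.1%), the median difference was -0.67 and limma's fry gave a p of 0.0048. The 25 genes lower on the mean VIP effect had medians of -0.72 and -0.38, with a median difference of 0.31 and a fry p of 0.021.

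**Figure D1:**
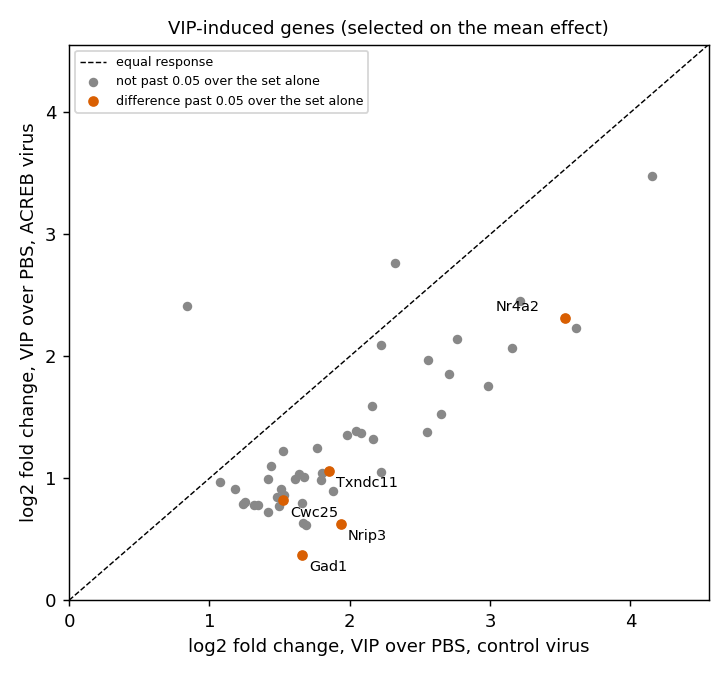
Log2 fold change of VIP over PBS with ACREB (y axis) against control virus (x axis) for the 48 genes with a mean VIP effect of at least 1; each point is a gene and the dashed line marks an equal response. 46 of the 48 lie below the line, and the 5 genes in orange passed 0.05 for the difference when adjusted over the set alone.

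No single gene passed edgeR's quasi-likelihood test of the interaction with Benjamini-Hochberg adjustment over all genes, with 0 higher and 0 lower (smallest adjusted p = 1). The block and DESeq2 also gave 0 (smallest adjusted p = 0.935 and 0.100). At an unadjusted p under 0.05 there were 201 genes with edgeR, 461 with the block and 216 with DESeq2. A uniform spread of p-values would give 838.05. Regroupings of the virus labels that were balanced over the numbers, as the real grouping is, gave a median of 302 with edgeR. The 838.05 is therefore not the count that chance gives in this fit. Adjusted over the set of 48 genes alone, Nr4a2 (-1.21, SE 0.27), Txndc11 (-0.79, SE 0.18), Nrip3 (-1.31, SE 0.35), Cwc25 (-0.71, SE 0.19) and Gad1 (-1.29, SE 0.35) passed. Ppp1r3c (-0.56, SE 0.25) and Dio2 (-1.38, SE 0.64) did not. Nrip3 and Cwc25 lie outside the naming rule and were chosen after their values were seen. Over the 53 genes chosen in control virus 8 passed, which is not independent evidence because the set was selected on these samples. Each other fit chose its own set by the same rule, and with the replicate block 45 of 105 passed. The count was 0 without ACREB VIP library 2 or 3, 1 without ACREB PBS library 2, 2 without ACREB PBS library 3 or control VIP library 1, and 13 without ACREB VIP library 1. It was 15 without control VIP library 2, 16 without control PBS library 2 and 20 without control PBS library 3.

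The 48 genes were selected for a rise with VIP, which favours higher values with VIP in these libraries. In each numbered pair their mean log2 CPM was higher with VIP, by 2.40, 1.98 and 1.56 with control virus (mean 1.98 ± 0.423, SD, n = 3) and by 1.64, 1.15 and 1.04 with ACREB (1.27 ± 0.318). An exact two-sided permutation test of these 6 differences gave p = 0.2, and the smallest possible is 0.1. Within each number the rise with ACREB minus that with control virus was -0.76, -0.84 and -0.52 (mean -0.71 ± 0.169, SD, n = 3), and an exact two-sided sign-flip test of these 3 differences gave p = 0.25, the smallest that 3 pairs allow. The cAMP/CREB target list was lower in the interaction by camera (median -0.33, adjusted p = 4.16e-09) and with an estimated correlation (adjusted p = 0.018), but not by fry (adjusted p = 0.131). Phosphodiesterases were lower by camera (median -0.29, adjusted p = 0.040) but not with an estimated correlation (adjusted p = 0.506). The call of phosphodiesterases was also lost without control PBS library 1 (0.164) or 2 (0.091), control VIP library 1 (0.136) or 2 (0.195), ACREB PBS library 3 (0.191), or ACREB VIP library 2 (0.063) or 3 (0.130). Adjusted over the list alone, Nr4a2 passed among cAMP/CREB targets and Gad1 among neuron markers.

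**Figure D2:**
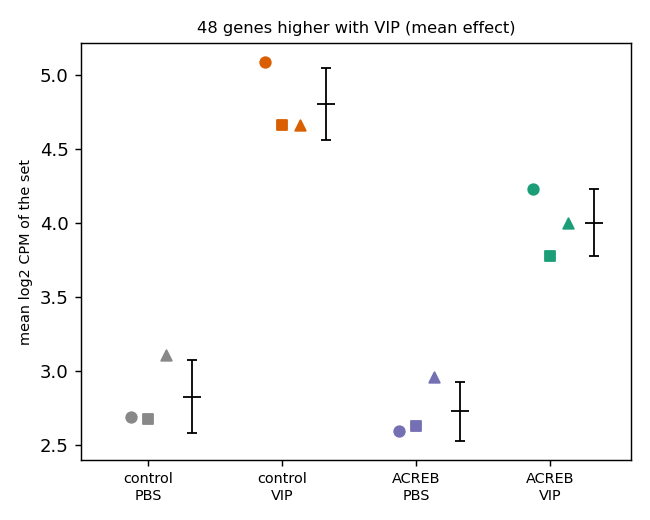
Mean log2 CPM of the 48 VIP-raised genes (y axis) in the 12 libraries by group (x axis); circles, squares and triangles are replicate numbers 1, 2 and 3, and bars show the mean ± SD of each group. ACREB VIP libraries (3.77 to 4.23) lie below control VIP libraries (4.66 to 5.08), and PBS libraries of both viruses span 2.59 to 3.11.

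The fourth comparison asked what ACREB changed without VIP. Mbd6, a methyl-CpG-binding domain protein gene, fell from 136.4 ± 38.1 to 34.7 ± 6.32 CPM (SD, n = 3). Helz2, a helicase co-activator gene, fell from 15.3 ± 1.93 to 7.47 ± 0.382 CPM, and Coq2, of coenzyme Q synthesis, from 44.4 ± 5.47 to 25.1 ± 2.16 CPM. Mturn rose from 46.8 ± 4.46 to 88.6 ± 5.71 CPM, although it overlaps Gm28402. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1 gene rose and 5 fell, with log2 changes of 0.92 for Mturn (SE 0.13, adjusted p = 0.040), -1.97 for Mbd6 (SE 0.22, 0.021), -1.09 for Fahd2a (SE 0.14, 0.038), -1.04 for Helz2 (SE 0.15, 0.040), -0.87 for Lrrc57 (SE 0.12, 0.038) and -0.83 for Coq2 (SE 0.12, 0.042). Lrrc57 overlaps Haus2. With the replicate block 14 genes rose and 23 fell, and DESeq2 called 44 and 73.

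Among 30 cell cycle genes 0 passed alone by edgeR, over all genes or adjusted over the list alone, but 29 were negative (median -0.27). The list was lower by camera (adjusted p = 2.10e-09), with an estimated correlation (adjusted p = 0.0084) and by fry (adjusted p = 0.00035). Of 25 interferon response genes 24 were negative (median -0.36), and Irf7 (-0.94) and Usp18 (-0.77) passed adjusted over the list alone, although they overlap Phrf1 and Gm44148 on the opposite strand and are uncertain. That list was lower by camera (adjusted p = 5.46e-10) but not with an estimated correlation (adjusted p = 0.083), and fry gave 0.071 without and 0.026 with the block. All 18 microglia markers were positive (median 0.37, camera adjusted p = 0.00083), a call lost with an estimated correlation (adjusted p = 0.796). Sterol synthesis and reactive astrocyte markers were lower by camera (adjusted p = 0.0084 for both), with adjusted p = 0.761 and 0.242 with an estimated correlation. The cAMP/CREB target list did not differ in this test (median 0.00, camera adjusted p = 0.921). With the block, camera also called ependymal markers higher (adjusted p = 0.0021, without it 0.126) and oligodendrocyte markers (0.0062, without it 0.0687) and stress response genes (0.044, without it 0.083) lower. With an estimated correlation, run without the block only, these 3 lists had adjusted p = 0.820, 0.619 and 0.761. Fry passed with the block for reactive astrocyte markers (adjusted p = 0.026), ependymal markers (0.018), cAMP receptor genes (0.026) and the circadian clock (0.049), where without it the values were 0.270, 0.710, 0.369 and 0.661.

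The libraries of both viruses were apart for each of these 6 genes, as the naming rule required. Mbd6 lay at 92.9 to 163.8 against 28.2 to 40.8 CPM and Lrrc57 at 30.5 to 34.4 against 16.2 to 19.9 CPM. Coq2 lay at 39.5 to 50.3 against 23.4 to 27.5 CPM. The adjusted p of the 6 genes lay near the threshold. All 6 calls were lost even without any 1 control VIP library, which is outside this comparison. Mturn lost its call without any 1 of the 12 libraries (adjusted p = 0.053 to 0.245, edgeR), and 0 genes rose in each of these fits except that without ACREB VIP library 1, where 1 rose. The count of falls was 2 without control PBS library 2 or ACREB VIP library 1, 1 without control PBS library 1 or ACREB VIP library 2, and 0 without any 1 of the others. With both PBS libraries numbered 2 left out, 0 genes rose and 0 fell. Camera lost its call of microglia markers without control PBS library 1 (adjusted p = 0.304) or ACREB PBS library 3 (0.219). It lost sterol synthesis without control PBS library 1 (0.077) or 2 (0.150) or ACREB PBS library 3 (0.219), and reactive astrocyte markers without control PBS library 2 (0.178) or ACREB PBS library 3 (0.053).

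The fifth comparison asked what ACREB changed in the presence of VIP. Nr4a2 was lower with ACREB (21.1 ± 0.954 against 58.1 ± 3.95 CPM; SD, n = 3), as were Txndc11 (50.2 ± 1.86 against 92.8 ± 11.8 CPM), Mbd6 (36.2 ± 7.73 against 127.7 ± 1.68 CPM) and Helz2 (8.70 ± 0.407 against 22.4 ± 3.01 CPM). Glyctk, a glycerate kinase gene that overlaps D030055H07Rik, rose from 3.94 ± 0.452 to 12.8 ± 3.19 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3 genes rose and 6 fell, with log2 changes of 1.70 for Glyctk (adjusted p = 0.015), 0.92 for Mturn (0.027), -1.82 for Mbd6 (0.015), -1.46 for Nr4a2 (0.015), -1.36 for Helz2 (0.011), -0.96 for Fahd2a (0.041) and -0.88 for Txndc11 (0.027). Lrrc57 (-0.84) and Gzmb, which encodes granzyme B, also passed but lie outside the naming rule and were chosen after their values were seen. Gzmb averaged 0.0171 ± 0.0295 CPM with control virus and VIP and 1.30 ± 0.140 CPM with ACREB and VIP (SD, n = 3). With the replicate block 25 genes rose and 36 fell, DESeq2 called 48 and 86, and library size without scaling factors gave 5 and 6. Nr4a1 (-1.29) passed with the block only (adjusted p = 0.025, edgeR).

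Of 30 cAMP/CREB target genes, Nr4a2 fell over all genes tested, and adjusted over the list alone Ppp1r3c (-0.78) and Pde10a (-0.73) passed too. The list was lower by camera (median -0.25, adjusted p = 4.52e-11) and with an estimated correlation (adjusted p = 0.0059). Of 30 cell cycle genes 0 passed alone by edgeR, over all genes or adjusted over the list alone, but 29 were negative (median -0.29). That list was lower by camera (adjusted p = 7.44e-12) and with an estimated correlation (adjusted p = 0.0039). All 25 interferon response genes were negative (median -0.46), and the list was lower by camera (adjusted p = 2.36e-17), with an estimated correlation (adjusted p = 0.012) and by fry (adjusted p = 0.010). Oasl1 (-1.83), which overlaps Gm13822, and Irf7 (-0.81) passed adjusted over that list alone, and both counts are uncertain. All 18 microglia markers were positive (median 0.46, camera adjusted p = 4.10e-06), a call lost with an estimated correlation (adjusted p = 0.527), and fry gave 0.567 without and 0.015 with the block. Reactive astrocyte markers and sterol synthesis genes were lower by camera only, with adjusted p = 0.240 and 0.482 with an estimated correlation. Both lost the call without control VIP library 2 (0.121 and 0.187), and reactive astrocyte markers also without ACREB VIP library 1 (0.069). The cAMP receptor list passed fry (adjusted p = 0.018) but not camera (0.187). With the block, camera called endothelial (adjusted p = 0.034, without it 0.230) and ependymal markers (0.0014, without it 0.065) higher, of which 3 of 9 and 7 of 9 were tested. With an estimated correlation, run without the block only, the adjusted p was 0.593 for both. Fry passed with the block for these 2 lists (adjusted p = 0.015 and 0.011, without it 0.567 for both) and for reactive astrocyte markers (0.015, without it 0.172).

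**Figure D3:**
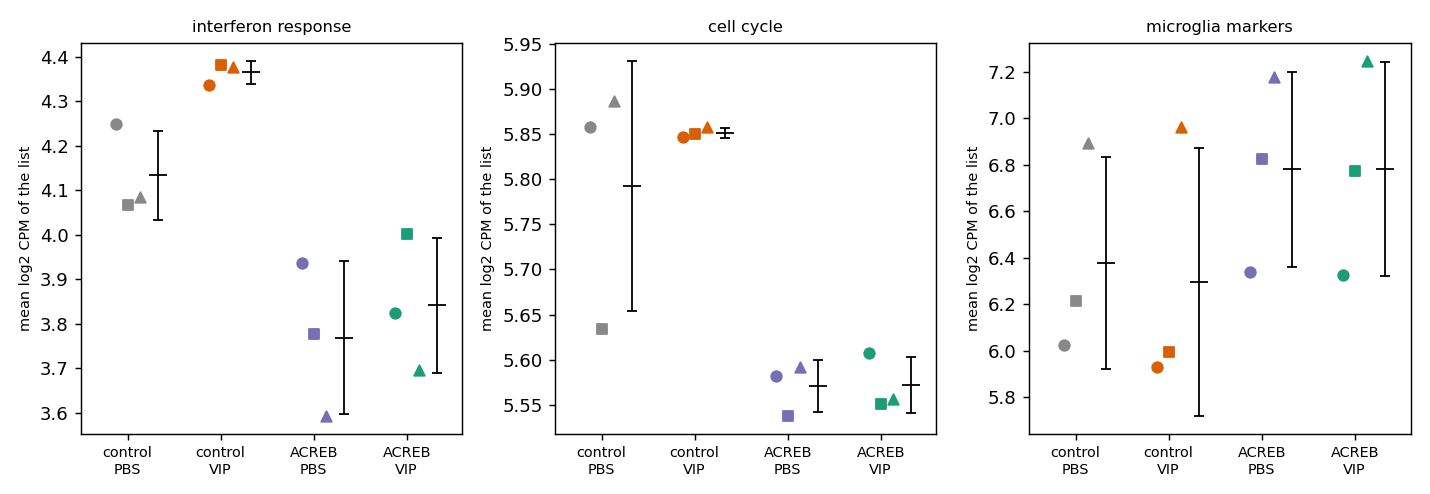
Mean log2 CPM of the interferon response, cell cycle and microglia lists (y axis) in the 12 libraries by group (x axis); circles, squares and triangles are replicate numbers 1, 2 and 3, and bars show the mean ± SD of each group. In all 6 pairs of the same number and treatment, the ACREB library was lower in the first 2 lists and higher in microglia markers.

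In the 6 pairs of the same number and treatment, the difference of ACREB from control was -0.68 to -0.29 for the interferon list, -0.30 to -0.10 for the cell cycle list and 0.28 to 0.78 for microglia markers, on the log2 scale. For microglia markers it was 0.32, 0.61 and 0.28 with PBS and 0.39, 0.78 and 0.28 with VIP in numbers 1 to 3. The differences of a number were alike, so the 6 pairs are not 6 separate results. With VIP too the libraries of genes named for this contrast were apart, as the naming rule required. Nr4a2 lay at 54.1 to 62.0 against 20.2 to 22.1 CPM and Mbd6 at 125.9 to 129.2 against 28.2 to 43.6 CPM. The calls changed with the libraries in the fit. Without control PBS library 2, 10 genes rose and 31 fell, and with both PBS libraries numbered 2 left out 11 rose and 36 fell. Without any 1 ACREB VIP library, or control VIP library 1 or 2, 0 rose and 0 fell, and without control VIP library 3 the counts were 0 and 1. Without ACREB PBS library 3 or control PBS library 3 they were 1 and 3.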

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

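The tests of GC content and gene length, of a swapped label, of gene selection, of regrouped whole pairs and whole numbers and of fits without control PBS library 2 were chosen only after the results were seen.

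The VIP response differed between the viruses in tests over sets of genes, while no single gene passed over all genes (smallest adjusted p = 1, edgeR). Over the 48 genes higher on the mean VIP effect the median difference in response was -0.67 (a p of 0.015 by limma's fry), and over the 25 genes lower it was 0.31 (a p of 0.021). Adjusted over the set alone by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the difference passed for Nr4a2 (-1.21, adjusted p = 0.020), Txndc11 (-0.79, 0.020), Nrip3 (-1.31, 0.032), Cwc25 (-0.71, 0.032) and Gad1 (-1.29, 0.032). By camera it passed for the cAMP/CREB target list (median -0.33, adjusted p = 4.16e-09) and for phosphodiesterases (median -0.29, adjusted p = 0.040). With an estimated correlation the adjusted p was 0.018 and 0.506, and by fry 0.131 and 0.784, so the call of phosphodiesterases was lost in both and that of cAMP/CREB targets by fry. Both lists hold Pde4b, Pde4d and Pde10a, so they are not separate results.

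The smaller response with ACREB was weighed against 4 technical explanations. Selection on the control-virus contrast is argued against by the median of -0.67 over genes selected on the mean of both viruses. Control PBS library 2 is argued against by -0.73 without it (a p of 0.021 by limma's fry), and GC content with gene length by -0.67 with offsets (a p of 0.022). Regroupings of the 6 whole pairs of a VIP and a PBS library are too few for a share under 0.05: 1 of 10 gave as large a median difference (real value -0.72, highest other 0.64). Swaps of virus labels within number and treatment were a test set beforehand. Of 32 swaps 7, the real grouping included, gave as large a difference (highest other 0.85). That meets the bound set for chance, a share of at least 0.05. The test cannot decide, however, since swaps of PBS labels alone hardly move the difference (0.66 to 0.85 in size). All 7 were among the 8 that leave the VIP labels together. Of the 24 that move VIP labels too, 0 gave as large a difference (highest 0.42). This parting of the swaps was not in the preset test, so chance stays open. A different state of the cultures, an effect of the virus preparations and a different share of microglia, whose markers were higher with ACREB in all 6 pairs (0.28 to 0.78), were not tested. Inhibition of CREB may explain the difference, as 1 hypothesis among these, and it was not tested on its own because the planned motif test was not run. The microglia mean log2 CPM of PBS libraries 1 to 3 was 6.0, 6.2 and 6.9 with control virus. With ACREB it was 6.3, 6.8 and 7.2. The VIP rise of the 48 genes fell in the same order, at 2.40, 1.98 and 1.56 and at 1.64, 1.15 and 1.04. Control pair 3 nevertheless rose more than ACREB pair 2, where this mean was lower. Number and microglia markers cannot be told apart within a virus.

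Control PBS library 2 stood apart from the other 11 libraries. GC content and gene length explained 53.5% of the variance of its departure, but its SD around the median library stayed at 0.438 after this trend was removed, above the 0.287 of the next library, so the trend is not the whole departure. ACREB PBS library 2 departed along the same component (34.6 against 81.2, 32.0% explained), and the 2 departures from the group means correlated at 0.679, so part of the departure is shared by the number. Its mean log2 CPM of the 48 VIP-raised genes lay 1.98 below the lowest control VIP library, but these genes were selected with it labelled PBS, which favours a low value. For the cAMP/CREB target list, fixed beforehand, its mean log2 CPM was 4.92. The other control PBS libraries had 4.68 and 5.02, and the control VIP libraries 5.69 to 5.85. These values argue against a label swapped with a control VIP library. Cells of another type stay open, since the highest median among 6 other cell type lists was 0.526, for fibroblasts and mural cells, between the bounds of 0.5 and 1 set for this test. That list was also raised in the other 3 libraries numbered 2 (0.24 to 0.30), and below 0 in the 8 remaining libraries. Apart from these cell type lists, no biological explanation was tested.

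The interferon response list was lower with ACREB by camera in both treatments, but with PBS the call was lost with an estimated correlation (adjusted p = 0.083) and by fry (adjusted p = 0.071). Microglia markers were higher with ACREB in all 6 pairs of the same number and treatment in which the interferon list was lower, and a different share of microglia was not tested as a source. Control PBS library 2 is argued against by a median of -0.37 with PBS without it (a p of 0.016 by limma's fry), and GC content with gene length by a mean of the medians of -0.41 with offsets (a p of 0.00017). Chance stays open. Among 32 label swaps within number and treatment 1, the real one, gave as large a mean effect (real value -0.42, highest other 0.36). This list was, however, picked from 22 after its values were seen. Of the 22 lists 6 gave such a count, more than the 0.69 that chance alone gives. The lists share libraries and some share genes, so this excess does not decide the question. Swaps that keep each number whole are too few for a share under 0.05 (1 of 4, highest other 0.23). A different state of the cultures at transduction was not tested, and neither was an effect of the virus preparations, so inhibition of CREB is 1 of several explanations that may apply.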

How the results depend on the processing

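The offsets for GC content and gene length, alone and with the replicate block, and the fits without both PBS libraries numbered 2 were chosen only after the data were seen.

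For VIP in control virus (71 rises, 11 falls) the counts were 186 and 71 with DESeq2, 184 and 90 with the replicate block, 132 and 19 with GC and length offsets, and 369 and 213 with these offsets and the block. Rises were 115 with no filter, and falls 17 without both PBS libraries numbered 2. The 6 libraries compared alone, with fewer residual degrees of freedom, gave 2 and 0. Leaving out 1 library gave 25 to 80 rises and 0 to 11 falls. For VIP with ACREB (2 and 0) the counts were 25 and 2 with DESeq2 and 39 and 8 with offsets and block. Rises were 13 with no filter, 13 with the block, 5 with offsets, 1 with 6 libraries and 1 to 5 leaving out 1 library.

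For ACREB with PBS (1 and 5) the counts were 44 and 73 with DESeq2, 6 and 9 with no filter, 14 and 23 with the block, 6 and 14 with offsets, and 126 and 170 with offsets and block. They were 0 and 0 without both PBS libraries numbered 2 and with 6 libraries, and 0 to 1 and 0 to 2 leaving out 1 library. For ACREB with VIP (3 and 6) they were 48 and 86 with DESeq2, 5 and 13 with no filter, 25 and 36 with the block, 9 and 34 with offsets, 242 and 343 with offsets and block, and 11 and 36 without both PBS libraries numbered 2. Library size only gave 5 rises, and leaving out 1 library 0 to 10 and 0 to 31. The cause of these differences was not tested.

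Of the 53 VIP-raised genes, 8 passed the interaction adjusted over the set alone. Each other fit chose its own set by the same rule, so its count is not out of these 53 genes. The count was 45 of 105 with the block, 21 with offsets, 47 with both and 13 without both PBS libraries numbered 2. It was 0 to 20 leaving out 1 library, and 5 of 48 with selection on the mean effect. The median difference stayed between -0.76 and -0.54 leaving out 1 library, and the share retained between 50.1% and 62.4%. The interaction over all genes gave 0 in every setting run with edgeR and with DESeq2. At an unadjusted p under 0.05 it gave 201 and 216, where a uniform spread of p-values would give 838.05. The mitochondrial list with VIP in control virus changed direction with offsets (camera adjusted p = 0.898) and with offsets and block (0.524).

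Of 42 named calls, 42 were kept with the block, DESeq2, DESeq2's size factors, the stricter filter and offsets with block. Library size only lost 2, no filter 1, offsets 3, leaving out both PBS libraries numbered 2 lost 9 and 6 libraries 34. The block added calls in edgeR's test. They were Trmt61b (adjusted p = 0.090, block 0.0057) and Tacr1 (0.353, block 0.042) for VIP with ACREB, Glyctk (0.113, block 0.019) for ACREB with PBS, and Coq2 (0.070, block 0.027) and Trmt61b (0.205, block 0.019) for ACREB with VIP. Beyond these and the calls given in the report, the block changed no other call of a gene named by the rule or of a list. Splits of 3 against 3 libraries are too few for a share under 0.05: 1 of 10 gave as many genes, with real counts of 82, 2, 6 and 9 and highest others of 0, 0, 1 and 0. The highest other of 1 came from a split that kept pairs together. For the interaction the real count was 0, which 100 of 100 splits drawn reach whatever the data, so the count decides nothing. At an unadjusted p under 0.05 the real grouping gave 201 genes. The median was 516 in the other splits and 302 in the 19 of them balanced over the numbers as the real one is. Of the 99 others 4 had any gene past the adjusted threshold. The highest, 113, came from the split that exchanged the virus labels of all VIP libraries, which by its construction adds up the virus effects of both treatments, and the other 3 gave 1 or 2. The test of CREB binding motifs was not run. At this depth and replication, simulated differences of 1 on the log2 scale were recovered for 27% of genes in the interaction. The simulation held no effect of replicate number and no outlying library, so recovery in the real data was not measured and may be lower.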

Other observations

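The genes in the next paragraph and the 6 lists after it were chosen, and tested, only after their values were seen.

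Of 4 genes picked for their values, 0 passed for ACREB without the replicate block, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With PBS, the class I genes H2-D1 (-1.05, adjusted p = 0.380, block 0.035) and H2-K1 (393.6 CPM with control virus and 196.7 CPM with ACREB, 0.341, block 0.037) had lower values with ACREB, as did H2-Q6 (-2.78, 0.131, block 0.035). With VIP, H2-D1 (adjusted p = 0.546, block 0.0499) and H2-Q6 (0.173, block 0.036) also passed with the block, in the same direction. H2-Q6 has near-identical copies, so its counts are uncertain. Cd74, the class II invariant chain, which overlaps Mir5107, was higher with PBS (1.85, adjusted p = 0.130, block 0.019) and with VIP (2.05, 0.070, block 0.015) in the same edgeR fits.

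Averaged over both treatments, the virus effect was -0.42 for the interferon response list, -0.26 for cell cycle genes, 0.46 for microglia markers, 0.41 for ependymal markers, -0.12 for reactive astrocyte markers and -0.13 for sterol synthesis. The fry p was 0.00029, 9.18e-07, 0.158, 0.210, 0.0095 and 0.066, and with the block 0.00031, 9.30e-06, 0.0018, 0.00024, 0.00092 and 0.011. These are 6 of 22 lists, and 2 genes, Cxcl10 and Gbp2, which overlap Art3 and Mir6381 on the opposite strand, are in both the interferon and the reactive astrocyte list.

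A hypothesis set before its result was that genes next to a VIP-raised gene rise with it. The median log2 fold change of 65 neighbours that were not raised themselves was 0.0109, at percentile 78.4 of 10000 random sets, which leaves the hypothesis undecided. Among raised neighbours, Eprs (1.80) and 4930532G15Rik (2.71) lie 179 bp apart on chromosome 1.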
